A study of Mus musculus with 6 samples.

How the data were processed

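RNA of 6 samples of RAW264.7 cells was sequenced, 3 per group. Per the labels' protocols the cells were stimulated with LPS for 24 h before the medium was exchanged for cement extract, RNA was purified with an RNeasy kit, and 1.3 ug of total RNA entered a SMARTER mRNA library kit. Groups were taken from the sample titles (LPS_ES_PMMA and LPS_PMMA), and columns of the deposited table were tied to samples by the name in each title or description. The replicate numbers come from the titles.

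The deposited table holds 1 line per lncRNA transcript with 6 columns of counts, 6 of FPKM and the authors' comparison. The counts are the authors' whole-number reads per transcript, per the file headers, with no normalization, and the smallest total over the 6 libraries was 3. The aligner, the counter and its strand setting are not given in the sources used here. The FPKM values are the authors', per the file headers; length times FPKM over count was 1 constant per library, which implies library totals of 4.50, 2.48 and 4.31 (LPS_ES_PMMA 1 to 3) and 4.48, 4.15 and 3.87 (LPS_PMMA 1 to 3) in units of 1e+06 reads. The log2 fold change of the authors' deposited table equals the log2 ratio of its group mean FPKM values, and it is infinite for 3282 features in which 1 mean is 0. The p-value and q-value columns are the authors' from edgeR, per the name of the deposited file, with version and design not given in the sources used here. The ratio of q to p in the 40 smallest p-values was, for 37 of them within 0.001 of a whole rank, that of a Benjamini-Hochberg adjustment over 107001 features, more than the 24817 listed. The build mm10 is named in the submitters' processing notes. All numeric columns of the table other than positions were assigned a meaning, and 0 were left unused.

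Before the data were examined, the groups, the tests, the gene lists, the rule for named features and most alternatives were fixed. That plan took FPKM as the deposited unit, with limma as the main test, and provided that edgeR would be the main test if counts were found; counts were found, so limma on FPKM is an alternative. Features were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and the groups were compared with the edgeR 4.0.16 quasi-likelihood F-test without covariates in R 4.3.3. Benjamini-Hochberg adjustment ran over the 8873 features tested, with a threshold of 0.05. Fitted log2 fold changes use edgeR's prior count of 0.125. The standard error is the size of the log2 fold change over the square root of F and is approximate. CPM are counts divided by TMM-scaled library totals, which were 4.12, 1.97 and 2.97 in LPS_ES_PMMA and 2.03, 2.54 and 2.77 in LPS_PMMA, in units of 1e+06. Where a group held 0 reads in all its libraries, a bound was computed against 3 counts over the group; 3 counts in 1 library equal 0.811 to 2.67 CPM of the column totals. Intervals cover counting error only, since reads without molecular identifiers are not independent molecules. A bound limits only the group with 0 reads. It takes the other group at its observed counts, without their counting error or the spread between libraries, so the true lower limit may be smaller. The common biological coefficient of variation was 0.415.

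Replicates of a group were compared before use. Over features with at least 10 reads in a pair, chi-square per degree of freedom lay between 15.4 and 45.5, so no pair of libraries differed by as little as sampling noise. Pearson's correlation of log2(FPKM + 0.1) across features lay between 0.746 and 0.815.

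Named features are (a) NONMMUT104330.1 and features tied to Ddx58; (b) the 10 largest and 10 smallest log2 fold changes among features past the threshold whose groups did not overlap and whose higher group mean FPKM was at least 1, with 1 feature per gene; (c) up to 5 members per list by mean FPKM; and (d) the 5 features with the highest mean FPKM. Called members of the lists are named too where few passed. NONMMUT104330.1 and the Ddx58 feature were removed by the filter on low counts and were read from the same fit without it.

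The 16 gene lists were lncRNAs described in LPS-stimulated macrophages, ubiquitous and imprinted lncRNAs, snoRNA hosts, microRNA hosts, small structured RNAs, inflammatory LPS and NF-kB response genes, alternative (M2) activation genes, RIG-I and interferon genes, NRF2 oxidative stress genes, integrated stress and unfolded protein response genes, proliferation genes, osteoclast genes, sterol genes, glycolysis and hypoxia genes, markers of other cell types, and macrophage identity genes. Features were tied to the protein-coding lists by the table's gene column or by overlap with or a distance of at most 10 kb from a gene of GENCODE M21, and to the lncRNA lists by their own name. At 10 kb, ties by position were restricted to annotated features after assembled positions were seen not to match the annotation. Lists with at least 5 tested features were tested with camera of limma 3.58.1 (correlation 0.01, 2-sided), with an estimated correlation and fry as alternatives. A distance of 250 kb was added after features that fell had been seen near interferon genes and after the displaced positions had been seen; it was the only wider distance run. At 250 kb that restriction was dropped: assembled transcripts were tied by position too, and position was used for the lncRNA lists as well. Classes of the table were tested with Fisher's exact test, adjusted over 20 tests.

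Alternatives were DESeq2 1.42.0, no filter, a mean FPKM of at least 1, sums per gene, the replicate number as a block, limma on log2(FPKM + 0.1) with pseudocounts 0.01 and 1, other filters, quantile or median-of-ratios scaling, no trend and robust fitting, and each library left out in turn. Chosen after the data were seen were library totals implied by FPKM, column totals, median-ratio factors, robust edgeR, thinned counts, a fit without the 10 features with the most counts, the distance of 250 kb, the sum of NONMMUT104330.1 with all features that overlap it, and bounds with each library left out.

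The fits were tested on simulated data made from the real means, spreads and library sizes of LPS_ES_PMMA against LPS_PMMA with 200 changed features. A first simulation used folds of 2 and 4, and when edgeR made no call there the folds were raised to 4 and 16. At 4-fold and 16-fold edgeR recovered 39% and 79% of changed features over 7777 features, with 2 of 120 calls false; DESeq2 recovered 56% and 78%, with 13 of 147 calls false. Another draw at 2-fold and 4-fold is kept among the results: over 7910 features edgeR recovered 0% and 10%, with 4 of 14 calls false, and DESeq2 5% and 45%, with 18 of 68 false. A list of 13 features moved by -1 on the log2 scale had adjusted p = 2.53e-07 by camera, and 0 of the other lists passed. Features were drawn independently and all members moved alike, so this does not test camera on members that share reads or move both ways. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Protein-coding genes and microRNAs were not analysed here, and 1 feature that the rule would name is not reported here.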

Results

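Long non-coding RNAs (lncRNAs) were measured by RNA sequencing in RAW264.7 cells, a mouse macrophage line, in 6 libraries that form 2 groups of 3. The cells were stimulated with lipopolysaccharide (LPS) for 24 h and then kept in medium conditioned by bone cement made of polymethyl methacrylate (PMMA). The cement of the LPS_ES_PMMA group contained enoxaparin sodium, a low-molecular-weight heparin, and that of the LPS_PMMA group did not. The titles and treatment labels of the control libraries name PMMA, whereas their descriptions and the columns of the deposited table name LPS alone, so whether these cells received plain cement extract rests on the titles and treatment labels. Nothing says that the 3 libraries of a group came from separate cultures, and p-values then measure the spread between these samples, which may be technical. The table listed 24817 features, of which 2541 had Ensembl transcript identifiers, 19971 had NONCODE identifiers (NONMMUT) and 2305 were transcripts assembled by the authors (MSTRG). Total counts over these features were 3261653, 1123551 and 3070657 in LPS_ES_PMMA 1, 2 and 3, and 3697638, 3249485 and 2877523 in LPS_PMMA 1, 2 and 3.

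The 5 most abundant features took between 46.6% (LPS_ES_PMMA 2) and 78.2% of the counts of a library. The feature with the highest mean FPKM, MSTRG.12264.1 (chromosome 12, 69206069 to 69408256), held 268482 to 1872050 counts per library. MSTRG.12263.1 and MSTRG.12263.2 span the same interval; in LPS_ES_PMMA 2 they held 0 and 54283 counts, and in LPS_PMMA 1 they held 492349 and 15707, so reads of this interval may be divided differently between them in different libraries. Rmrp (ENSMUST00000157463), the RNA component of the RNase MRP ribonuclease, MSTRG.17528.3 and NONMMUT118967.1 completed the 5 features with the highest mean FPKM. None of the 5 passed the test between the groups, with adjusted p from edgeR between 0.327 for MSTRG.17528.3 and 0.601 for NONMMUT118967.1. The first principal component held 41.1% of the variance and separated the groups, with LPS_ES_PMMA libraries between -59.8 and -33.6 and LPS_PMMA libraries between 24.2 and 66.3. The TMM factors put the 6 libraries in the same order, from 1.82 in LPS_ES_PMMA 2 to 0.559 in LPS_PMMA 1. The component therefore cannot tell the groups apart from differences in library composition.

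Positions are given as the table lists them, for which the labels state build mm10. Of 2533 Ensembl transcripts found in the GENCODE M21 annotation of that build, 2517 had the same start and end. Both ends of assembled transcripts met those of protein-coding transcripts most often at an offset, of 11.6 to 726.8 kb in size, in 45 of 45 stretches of 10 Mb that could be read. Gene names below are therefore those that the table or the listed position ties to a feature. Whether counting used strand is not given in the sources used here, so reads of an antisense feature cannot be told apart from those of the gene opposite it, and overlapping features may share reads.

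The comparison of the groups asked which lncRNAs differ between cells kept in extracts of cement with and without enoxaparin. Among features that fell with enoxaparin, NONMMUT110310.1 (chromosome 2, 173049287 to 173050935, intergenic) went from 119.9 ± 20.8 CPM (counts per 1e+06 TMM-scaled counts; SD, n = 3) in LPS_PMMA to 1.93 ± 0.859 in LPS_ES_PMMA. NONMMUT084037.1 (chromosome 11, 83011479 to 83013585), listed as antisense to an exon of Slfn8, a member of the Schlafen family, went from 99.7 ± 21.6 to 0.674 ± 1.17 CPM. MSTRG.29280.1, which the table ties to the interferon-induced gene Ifit2, went from 22.6 ± 7.62 to 0.338 ± 0.585 CPM. Among features that rose, MSTRG.43759.9 (chromosome 5, 104582993 to 104588904) went from 3.25 ± 5.63 to 925 ± 351 CPM. MSTRG.51056.1, tied to the potassium channel subunit gene Kcne3, held no reads in LPS_PMMA and 13.9 ± 7.39 CPM in LPS_ES_PMMA.

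By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 422 of 8873 tested features passed an adjusted p of 0.05, 193 higher and 229 lower in LPS_ES_PMMA. The smallest adjusted p was 0.00206, and 1940 features had an unadjusted p under 0.05. Every one of the 422 changed by a log2 fold change of at least 1 in size, with a median size of 2.14 and a median standard error of 0.36. The median log2 fold change of all tested features was 0.03.

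NONMMUT110310.1 had a log2 fold change of -5.87 (SE 0.40, adjusted p from edgeR = 0.00206), and it alone among the 20 features with the largest changes passed in 6 of 6 fits that each left out 1 library. NONMMUT084037.1 fell by 7.11 on the log2 scale (SE 0.95, adjusted p from edgeR = 0.012), and MSTRG.29280.1 fell by 6.35 (SE 0.82, adjusted p from edgeR = 0.0106). MSTRG.40521.1 fell by 6.28 (SE 1.09, adjusted p from edgeR = 0.0227), from 273, 127 and 25 counts to 2, 1 and 4. MSTRG.43759.9 rose by 8.08 (SE 1.46, adjusted p from edgeR = 0.0259), with 0, 0 and 27 counts in LPS_PMMA. As listed, it overlaps the more abundant NONMMUT118967.1 and other assembled transcripts, with which it may share reads. It passed in 1 of 6 fits that left out a library, the fit without LPS_PMMA 3, where the controls held no reads (fitted log2 fold change 14.30), and not in robust edgeR (adjusted p from edgeR = 0.0888, of alternatives between 0.00264 and 0.0983). In the stretch of chromosome 5 from 100000001 to 110000000, 10 of 17 assembled transcripts met protein-coding transcripts at an offset of -147800 bp. Whether MSTRG.43759.9 or NONMMUT118967.1 holds reads of a protein-coding gene there was not tested.

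The other 6 of the 10 features that fell most had no reads in LPS_ES_PMMA, so that only a bound against 3 counts over the group can be given. Such a bound takes the counts of LPS_PMMA as observed, without their counting error. The bound was at least 41.1-fold lower for MSTRG.49961.1, 37.4-fold for NONMMUT066321.2 (Gm45449), 32.1-fold for NONMMUT039936.2, 30.8-fold for NONMMUT032074.2, 20.6-fold for NONMMUT049406.2 (9930104L06Rik) and 20.6-fold for MSTRG.11688.1. That of MSTRG.49961.1, with 64, 18 and 18 counts in LPS_PMMA, was 20.5-fold without LPS_PMMA 1. Its call was lost in 6 of 6 fits that left out a library, in robust edgeR (adjusted p from edgeR = 0.0529), with a replicate block and with the filter of a mean FPKM of at least 1; adjusted p of all alternatives was between 3.33e-06 and 0.122. NONMMUT032074.2 was even between libraries, with 24, 25 and 26 counts in LPS_PMMA (adjusted p from edgeR = 0.00954). It passed in 5 of 6 fits that left out a library, NONMMUT066321.2 and NONMMUT039936.2 in 3, MSTRG.11688.1 in 1 and NONMMUT049406.2 in 0. Of the 10 features that rose most, 9 had no reads in LPS_PMMA, and their bounds take the counts of LPS_ES_PMMA as observed. MSTRG.51056.1 was at least 29.7-fold higher, NONMMUT031052.2 14.6-fold, and MSTRG.31906.1, NONMMUT028032.2 and MSTRG.42378.1 (Mapre3) at least 11.3-fold. The bounds for NONMMUT109565.1, NONMMUT011348.2 (Ppm1e), NONMMUT126510.1 (Nova2) and NONMMUT128460.1 lay between 7.03-fold and 9.73-fold. These 9 features had adjusted p from edgeR between 0.0183 and 0.0404. MSTRG.51056.1 and NONMMUT031052.2 each passed in 1 of 6 fits that left out a library, and the others passed in none.

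The balance of higher and lower calls rested on how the libraries were scaled. TMM factors gave 193 higher and 229 lower, column totals without factors 302 and 68, and library totals implied by the FPKM columns 230 and 94, while the median log2 fold change of all tested features was 0.03, 0.82 and 0.45. Changes below are relative to the TMM scale unless said otherwise. Leaving out LPS_ES_PMMA 1, 2 or 3 left 54, 112 or 51 calls, and leaving out LPS_PMMA 1, 2 or 3 left 136, 50 or 125.

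**Figure D1:**
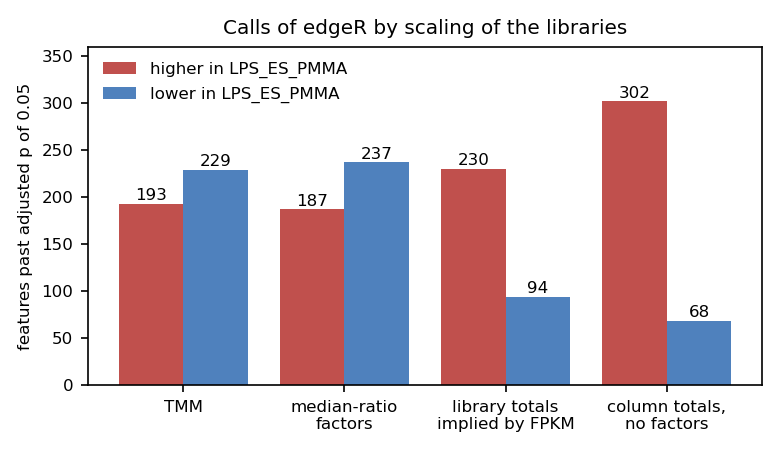
Number of features past an adjusted p of 0.05 in edgeR (vertical axis), higher (red) or lower (blue) in LPS_ES_PMMA, under each way of scaling the libraries. Higher calls ranged from 187 to 302 and lower calls from 68 to 237.

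The series title names NONMMUT104330.1, microRNA miR-709 and Ddx58, the gene of the cytosolic RNA sensor RIG-I, so these features were read separately. NONMMUT104330.1 (chromosome 18, 35055575 to 35087617, intergenic, 1516 nt) held 23 reads in LPS_PMMA 1 and 0 in each of the other 5 libraries. Too few for the filter on low counts, it was fitted without that filter and had a log2 fold change of -6.28 (SE 2.46, adjusted p from edgeR = 0.349). With reads in 1 library, every split of the libraries differs alike, so the planned exact permutation test could not tell the groups apart. The authors' deposited table gives p = 0.0201 and q = 0.259 for NONMMUT104330.1 and calls it down. Its 0 counts in LPS_ES_PMMA allow a bound of at least 9.46-fold lower, which rests on the reads of LPS_PMMA 1 alone. That bound takes these 23 reads without counting error, so it may overstate the fall.

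The 3 annotated features that overlap NONMMUT104330.1 held reads in 5 of the 6 libraries, and none in LPS_PMMA 1. NONMMUT031938.2 held 39, 15 and 33 reads in LPS_ES_PMMA and 0, 26 and 28 in LPS_PMMA. NONMMUT031937.2 held 9, 9 and 7 against 0, 6 and 7, and NONMMUT031940.2 held 12, 3 and 4 against 0, 5 and 9. Summed with NONMMUT104330.1, the 4 features held 60, 27 and 44 reads in LPS_ES_PMMA and 23, 37 and 44 in LPS_PMMA, a log2 fold change of 0.044 (SE 0.26, adjusted p from edgeR = 0.945). The assembled MSTRG.27037.1 (35042235 to 35065013) overlaps it too as listed, with 50, 14 and 36 reads in LPS_ES_PMMA and 34, 56 and 36 in LPS_PMMA; with it the sum had a log2 fold change of -0.32 (SE 0.25, adjusted p from edgeR = 0.503). No feature of the table is a Ddx58 transcript. NONMMUT147981.1 (chromosome 4, 40239839 to 40241242), listed as bidirectional with Ddx58, held 0 reads in each LPS_ES_PMMA library and 5, 1 and 2 in LPS_PMMA (log2 fold change -4.69, SE 1.67, adjusted p from edgeR without the filter = 0.306, exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow). A fitted fold change of such a feature depends on the prior count of 0.125. With the reads of LPS_PMMA taken as observed, the bound was at least 3.29-fold lower, and 1.71-fold without LPS_PMMA 1. miR-709 was not analysed here.

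**Figure D2:**
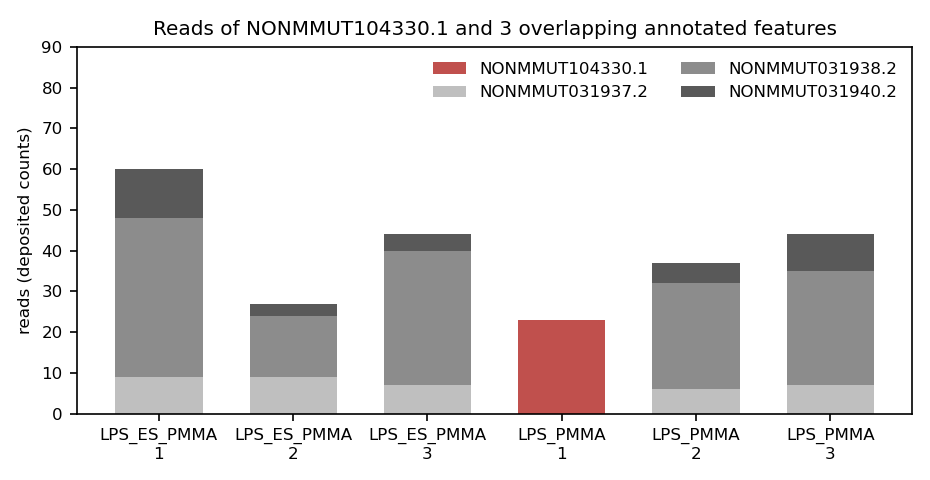
Deposited read counts (vertical axis) of NONMMUT104330.1 (red) and of 3 annotated features that overlap it (greys), stacked for each of the 6 libraries. The 23 reads of NONMMUT104330.1 lie in LPS_PMMA 1, the library in which the other features hold 0.

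Features were then grouped by genes fixed before the data were examined, through their own name, the table's gene column or, for annotated features, a listed position within 10 kb. That distance is shorter than the smallest offset found for assembled transcripts (11.6 kb). If reads were placed on another assembly, ties by position may not hold. The largest number of changes was among features tied to RIG-I and interferon genes, of which 36 were listed and 13 tested. Of these, 5 fell, 3 rose and 5 did not pass, and 8 passed when adjusted over the list alone. NONMMUT034527.2, within 10 kb of the interferon-induced gene Ifit3b, fell from 16.3 ± 1.39 to 0.805 ± 0.182 CPM. NONMMUT148390.1, near the gene of the ubiquitin-like protein Isg15, fell from 25.5 ± 4.74 to 2.31 ± 0.534 CPM. Both had adjusted p from edgeR of 0.00279 and 0.00343 and log2 fold changes of -4.31 (SE 0.37) and -3.47 (SE 0.33).

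The other members that fell were MSTRG.29280.1 and MSTRG.29277.1, both tied to Ifit2, and NONMMUT026433.2, tied to the ADP-ribosyltransferase gene Parp14, at -1.14 (SE 0.25, adjusted p from edgeR = 0.0472). The members that rose were NONMMUT150657.1, tied to the ISG15 protease gene Usp18, at 2.04 (SE 0.30, adjusted p from edgeR = 0.0159), and NONMMUT106143.1 and NONMMUT106142.1 near Ifit1, at 2.18 (SE 0.35) and 2.98 (SE 0.51). Of these calls, NONMMUT034527.2 and NONMMUT148390.1 passed in 6 of 6 fits that left out a library, MSTRG.29280.1 in 3, NONMMUT150657.1 in 2, MSTRG.29277.1, NONMMUT106143.1 and NONMMUT106142.1 in 1, and NONMMUT026433.2 in 0. As listed, the features near Ifit2, Ifit3b and Ifit1 all lie on chromosome 19 between 34547699 and 34659688. They are neighbours that moved both ways, and not separate loci. Camera with a preset correlation gave adjusted p = 0.0574 for the list as a whole (median log2 fold change -0.21, 7 of 13 below 0), which did not pass, and adjusted p = 0.217 with an estimated correlation. That median was 0.55 under column totals and 0.20 under totals implied by FPKM, and between -0.27 and -0.23 relative to all tested features under every scaling. Over all 126 tested features within 250 kb of a gene of this list, assembled transcripts tied by position included, 26 fell and 4 rose, and 44 passed when adjusted over the list alone. That distance was chosen after features that fell had been seen near interferon genes. There, camera gave adjusted p = 1.02e-07 and adjusted p = 0.0346 with an estimated correlation. The median log2 fold change of these 126 features was -0.34, or -0.37 relative to all tested features, and it was above 0 under column totals (0.45) and under library totals implied by FPKM (0.11), where the median of all features was higher still.

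**Figure D3:**
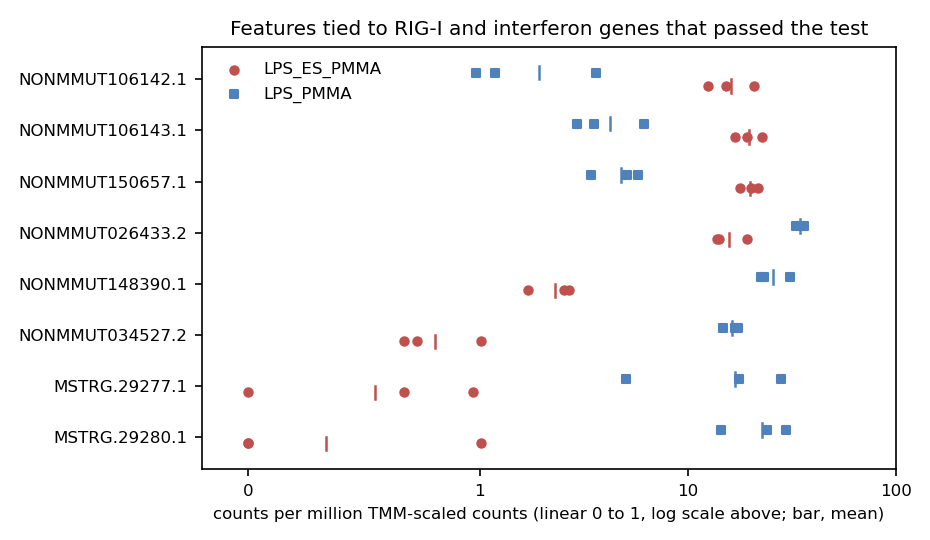
CPM on TMM-scaled totals (horizontal axis, linear from 0 to 1 and logarithmic above) of the 8 features tied to RIG-I and interferon genes that passed the test. Points are libraries of LPS_ES_PMMA (red circles) and LPS_PMMA (blue squares), 3 each, and bars are group means; the upper 3 features lie higher in every LPS_ES_PMMA library and the lower 5 in every LPS_PMMA library.

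Of 10 tested features tied to inflammatory LPS and NF-kB response genes 1 fell and none rose, and the list as a whole did not pass (camera adjusted p = 0.603, and 0.621 with an estimated correlation), and the median (0.036) and mean (-0.09) log2 fold change of the list differed in sign. The feature that fell, NONMMUT105607.1, is tied to the NF-kB subunit gene Nfkb2 and went from 15.2 ± 0.785 to 2.49 ± 0.448 CPM (log2 fold change -2.58, SE 0.32, adjusted p from edgeR = 0.00954, past in 3 of 6 fits that left out a library). NONMMUT011139.2, tied to the chemokine gene Ccl4, held 25.6 ± 2.53 CPM in LPS_PMMA and 26.5 ± 8.98 in LPS_ES_PMMA (adjusted p from edgeR = 0.949). NONMMUT084048.1, within 10 kb of the chemokine gene Ccl5, held 16.8 ± 23.7 CPM in LPS_PMMA and 55.3 ± 38.5 in LPS_ES_PMMA without passing (log2 fold change 1.70, SE 1.07, adjusted p from edgeR = 0.4). Of features tied to alternative (M2) activation genes, 1 of 15 had enough counts to be tested, ENSMUST00000118803 next to Mgl2, and it did not pass (41.5 ± 11.3 CPM in LPS_PMMA and 79.7 ± 83.4 in LPS_ES_PMMA, adjusted p from edgeR = 0.472). M2 genes themselves were not analysed here.

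Among 6 tested features tied to NRF2 oxidative stress genes, ENSMUST00000193524, in an intron of the cystine transporter gene Slc7a11, rose (log2 fold change 2.15, SE 0.34, adjusted p from edgeR = 0.0175). MSTRG.49995.1, tied to the ferritin light chain gene Ftl1, fell (-2.36, SE 0.51, adjusted p from edgeR = 0.0446). NONMMUT042943.2, over an exon of Slc7a11, lay lower without passing (-1.46, SE 0.36, adjusted p from edgeR = 0.0676). Both calls passed in 0 of 6 fits that left out a library. Adjusted over the list alone, 4 features passed, and the list as a whole did not pass (adjusted p from limma's camera = 0.49). Of features tied to markers of other cell types, 2 were tested and NONMMUT057375.2, next to Cd8a, rose from 10.1 ± 1.21 to 26.7 ± 7.47 CPM (adjusted p from edgeR = 0.0442, past in 0 of 6 fits that left out a library), while NONMMUT096548.1, opposite Krt8, did not pass (adjusted p from edgeR = 0.088); both passed when adjusted over the list alone.

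None of the lncRNAs in the lists matched by their own name was called by edgeR here. The authors' deposited edgeR comparison calls up Neat1 (ENSMUST00000173672, p = 0.0468, q = 0.436) and a Mir99ahg transcript (ENSMUST00000183333, p = 0.00411, q = 0.0883). Of 7 tested features of ubiquitous and imprinted lncRNAs, none passed (camera adjusted p = 0.603), among them Kcnq1ot1 (ENSMUST00000185789), an imprinted antisense transcript, at 656 ± 26.6 CPM in LPS_PMMA and 331 ± 98.4 in LPS_ES_PMMA (adjusted p from edgeR = 0.0923). All 5 tested features of microRNA host lncRNAs, from Dleu2 and Mir99ahg, had log2 fold changes above 0 without passing, with a median of 0.75 (camera adjusted p = 0.0574, and adjusted p = 0.217 with an estimated correlation), and 1 passed when adjusted over the list alone. The 1 tested lncRNA described in LPS-stimulated macrophages was Neat1 (ENSMUST00000173672), a scaffold of nuclear paraspeckles, at 28.3 ± 14.4 CPM in LPS_PMMA and 49.5 ± 6.5 in LPS_ES_PMMA (adjusted p from edgeR = 0.25). Rmrp was the 1 tested feature that its own name ties to the small structured RNAs. Whether assembled transcripts hold reads of others was not tested.

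Of 6 tested features tied to sterol genes none passed; 2 passed when adjusted over the list alone, and the list's median (-0.19) and mean (0.42) differed in sign (camera adjusted p = 0.49). None passed among the tested features tied to macrophage identity genes (4), integrated stress and unfolded protein response genes (2), proliferation genes (2) and glycolysis and hypoxia genes (2), of which 0, 1, 1 and 0 passed when adjusted over the list alone. No feature tied to snoRNA host lncRNAs or osteoclast genes had enough counts to be tested. By camera 0 of the 6 lists with at least 5 tested features passed, where 2 had an unadjusted p under 0.05 (interferon 0.0191, microRNA hosts 0.0173) and fry, which asks only whether a list moves one way, passed 3. Leaving out LPS_PMMA 3 gave the interferon list an adjusted p of 0.00652 by camera (all alternatives 0.00462 to 0.617).

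By the class the table gives, 2 of the 3 classes of assembled transcripts were called lower more often than other features. Of 438 tested features of class Intron LncRNA, 28 were lower (6.39%, against 2.38% of the others; odds ratio 2.80, Fisher's exact adjusted p = 0.000152). Of 799 of class Antisense LncRNA, 37 were lower (4.63% against 2.38%; odds ratio 1.99, Fisher's exact adjusted p = 0.00395). The remaining assembled class, Intergenic LncRNA, did not pass (17 of 397, 4.28% against 2.5%, Fisher's exact adjusted p = 0.14). Annotated features of class intronic_sense were called lower less often, in 24 of 1602 (1.5% against 2.82%; odds ratio 0.524, Fisher's exact adjusted p = 0.0112). The other 17 of 20 tests did not pass. Leaving out LPS_ES_PMMA 1, 2 or 3 or LPS_PMMA 2 left 0 of these tests past the threshold, leaving out LPS_PMMA 1 left 1, and leaving out LPS_PMMA 3 left 2; neighbouring features can share reads, so that the features counted are not independent.

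The authors' deposited table called 1693 features, 1075 up and 618 down with enoxaparin cement. Its calls follow a p under 0.05, a log2 ratio of at least 1 in size and a group mean FPKM of at least 1, and 479 of them have a q under 0.05. Of the 1693, 1039 had enough counts to be tested here and 381 (22.5%) passed, 190 up and 191 down, all 381 in the same direction. Of the 479, 290 (60.5%) passed. NONMMUT110310.1 and NONMMUT084037.1 are down in both, with q = 2.87e-19 and q = 4.32e-18 in the authors' deposited table. NONMMUT104330.1 is among 53 of the authors' calls with reads in a single library, of which 18 have q under 0.05; the filter used here removes such features before the test. The calls not tested here held a median of 29 reads over the 6 libraries, against 163 in those tested. Without LPS_ES_PMMA 1, 2 or 3 the overlap was 52, 106 or 50 features, and without LPS_PMMA 1, 2 or 3 it was 133, 47 or 117.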

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

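The fits with library totals implied by FPKM, column totals, median-ratio factors, robust edgeR, thinned counts, without the 10 features with the most counts and with list ties of 250 kb were tests chosen after the data were seen; the others were planned. Of the 422 calls, 386 were also calls of DESeq2, 258 of edgeR on column totals, 162 of limma on FPKM with pseudocount 0.1 (the test planned for FPKM alone) and 117 of limma without trend. Of 506 results of the 20 most changed features, 370 stayed past the threshold and 136 did not; the direction could not turn in the 9 with 0 reads in LPS_PMMA and the 6 with 0 reads in LPS_ES_PMMA. Against 422 calls (193 higher, 229 lower, 381 shared with the authors' deposited calls, 3 classes), edgeR without a filter gave 174 (64 higher, 110 lower, 173 shared, 7 classes), features with a mean FPKM of at least 1 gave 200 (71, 129, 196, 1 class), and thinning to the smallest library gave 237 (108, 129, 215, 0 classes). Column totals without factors gave 302 higher and 68 lower (81.6% higher, against 45.7%), and library totals implied by FPKM 230 and 94 (71.0% higher). Without the 10 most abundant features column totals gave 281 and 173 (61.9% higher), and without LPS_ES_PMMA 2 they gave 21 and 20. Sums per gene (5 classes) and DESeq2 (517 calls, 5 classes) stayed within 1.5 times in calls. limma on FPKM called 380 features with pseudocount 0.1 (100 lower, 6 classes), 297 with 1 (100 lower, 6 classes) and 505 with 0.01 (388 higher, 117 lower, 7 classes). limma without a filter called 120 (70 higher, 50 lower, 118 shared, 5 classes), with a mean FPKM of at least 1 105 (54, 51, 105 shared, 1 class), and with robust fitting 252 (83 lower, 226 shared, 6 classes). limma without trend gave 327 higher and 91 lower (232 shared, 1 class), per gene 310 and 111 (6 classes), with quantile normalization 145 lower (6 classes), and with median-of-ratios scaling 8 classes. An unadjusted p of 0.05 with a log2 of at least 1 gave 1439 features. Fewer features or reads enter the filtered and thinned fits; otherwise the cause was not tested.

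Leaving out 1 library gave 50 to 136 calls (10 to 44 higher, 36 to 92 lower), 47 to 133 shared with the authors' calls, 0 to 2 classes and 0 to 1 lists; 30 of 119 such results of the 20 most changed features stayed past the threshold, with fewer libraries in each fit. NONMMUT104330.1 ranged from -6.89 to -6.14, with no value without LPS_PMMA 1, where it holds no reads, and the Ddx58 feature from -5.09 to -3.78. NONMMUT104330.1 passed with thinned counts (-5.37, adjusted p from edgeR = 0.0208) and under the replicate block (-6.54, adjusted p from edgeR = 0.026), of 21 alternatives between 0.0208 and 0.629. Both calls rest on the reads of LPS_PMMA 1 alone, so they do not show a difference shared by the libraries of a group. The Ddx58 feature passed in none of 22 (0.139 to 0.691). Against 0 lists by camera, 1 passed under column totals, 1 under totals implied by FPKM, 3 by fry, and 1 with ties of 250 kb, by preset correlation, by estimated correlation (1) and by fry (1); the cause was not tested. With the replicate number as a replicate block edgeR called 41 features (10 higher, 31 lower, 41 shared with the authors' calls, 0 classes), 35 of them among the 422. Deviations of same-numbered libraries correlated at -0.0185, -0.0265 and -0.0901, so no pairing by number was seen. A small effect shared by same-numbered libraries is not excluded by these values. Depth limits features near 3 counts, which are 2.67 per 1e+06 counts of the column total (not TMM-scaled) in LPS_ES_PMMA 2.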

Other observations

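The tests of neighbouring features, of NONMMUT104330.1, of positions and of the number of calls were chosen after the results were seen; for the 250 kb interferon list the distance was chosen so, and its tests were written down before they were run. With gaps of at most 50 kb, 57 loci held at least 2 called features, 150 in all; whether calls lie closer together than tested features do was not tested. In 51 of the loci every call had the same direction, against a median of 23 and at most 36 when directions were shuffled (permutation p = 0.0001, the smallest that 10000 shuffles can give). Overlapping features can share reads, so these are not independent features. On chromosome 4, between 144938256 and 145007452, 8 of 9 tested features fell, with log2 fold changes of -4.85 to -3.0, in a stretch that the table ties to Vps13d. On chromosome 5, between 105879583 and 105962888, 9 of 22 fell (-1.96 to -1.07), and on chromosome 11, between 83066535 and 83083886, 5 of 6 fell (-3.37 to -2.89) in a stretch tied to the Schlafen gene Slfn2. All 4 tested features rose at 17:26644943 to 26665095 (1.82 to 3.18, tied to Ergic1) and at 8:4662218 to 4688494 (1.98 to 3.05). At 19:34622239 to 34661955, 3 features rose and 1 fell, among them those near Ifit1 and Ifit3b named above.

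Of assembled transcripts 82 fell and 36 rose of 1634 tested (median log2 fold change -0.40), whereas 136 fell and 143 rose of 6433 NONCODE features (median 0.11) and 11 fell and 14 rose of 806 Ensembl features (median 0.10). Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many calls as the groups did (422), namely the groups themselves, and the highest other gave 4; 10 splits are too few for a share under 0.05.

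The reads of NONMMUT104330.1 lay in LPS_PMMA 1 alone, where 3 overlapping features held 0 reads and 31.0 were expected from the other LPS_PMMA libraries. A fall of the whole locus by a log2 fold change of -1 or more in size is argued against by the sum of the 4 annotated features, at 0.044 (SE 0.26), and by the sum with the assembled MSTRG.27037.1, at -0.32 (SE 0.25); a smaller fall is not excluded. A candidate explanation is that reads of this locus were assigned to another transcript in that library. This stays open, because the sum in LPS_PMMA 1 (11.3 CPM) lay below the other 5 libraries (13.7 to 15.9), outside the range set for it, while with MSTRG.27037.1 it (28.0 CPM) lay within theirs (20.8 to 36.6).

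In the stretches that could be read, assembled transcripts met gene models of the stated build at an offset, where an offset of 0 could hardly be seen. If annotated features had been counted where the listed positions fall on another assembly, those over protein-coding exons at the offset of their stretch would hold more reads per base. The area under the curve was 0.560 there, 0.476 at the listed positions, 0.487 at mirrored offsets and at most 0.499 in 100 random draws, which argues against displaced assembled transcripts alone and is consistent with reads placed on another assembly than the annotation. Features counted in that way may hold reads of other genes than those named here. No biological explanation was tested.

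Features within 250 kb of RIG-I and interferon genes lay lower relative to all features, with 24 of 33 stretches of 500 kb having a median below 0. None of 10000 lists matched on abundance had a median as low (percentile 0), which argues against the fall of log2 fold change with abundance. Those lists were matched on abundance only. Assembled transcripts, which this list takes in by position, lay lower in the whole data (median log2 fold change -0.40, against 0.11 for NONCODE features). With 1 feature kept per stretch the list's unadjusted p by limma's camera was 2.08e-08, which argues against several features of a few loci as the only source. A few stretches with large falls are not excluded by it. Of the 10 splits, 1 gave a camera p as small (6.37e-09, the groups themselves; lowest other 0.0148), and 10 splits are too few for a share under 0.05. The features tied at 10 kb did not pass (adjusted p from camera = 0.0574, and adjusted p = 0.217 with an estimated correlation), and 3 of their 8 calls rose, near Usp18 and Ifit1. Displaced positions, the share of assembled transcripts in the list and reads shared between neighbours stay open, and a lower level around these genes with enoxaparin cement is only a hypothesis, which the mRNA of interferon-induced genes, not analysed here, would test.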
